A study of Mus musculus with 5 samples.

How the data were processed

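Whole-tumour RNA was profiled on Affymetrix Clariom S mouse arrays, which hold probes for well-annotated genes, with 1 array per tumour and 5 tumours in all. Each tumour came from its own mouse, so the replicates are separate animals. The deposited values are log2 signals, and the submitters' processing notes name the oligo package and RMA (background correction, quantile normalization and median-polish summary into 1 value per probe set). The versions and options of that step are not given in the sources used here. The scale was also tested on the values, which ran from 2.53 to 13.3 with nearly equal medians, as log2 RMA output does. No raw scanner files, scan dates or slide positions were used here, so batches of arrays could not be examined.

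The table held 22203 probe sets (called probes below), and none of its columns of per-sample values was left out. The platform annotation gave 1 gene symbol for 19572 probes, several for 0, and none for 2631, which are counted but unnamed here. All 19572 Entrez identifiers were found in the RefSeq gene table of the mouse assembly GRCm38.p6, and 0 symbols changed through them. No coordinates are printed, because the values name no genome build. For the 55 genes with several probes, the probe with the highest mean over the 5 arrays stood for the gene in gene lists and named genes. Among genes in a list or named by rule, 3 had several probes, and in 0 of them did the probes differ in their call.

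The only comparison the labels give is RG7112 minus vehicle, both with anti-PD-1. It was fitted in R 4.3.3 with limma 3.58.1 (lmFit on the deposited log2 values, then eBayes with default settings), with Benjamini-Hochberg adjustment over all 22203 probes and a call at adjusted p under 0.05. The authors' own test is not given in the sources used here. The fit had 3 residual degrees of freedom, to which the moderated variance added a prior of 7.92. For 37 gene lists, the per-tumour mean of the members' log2 signals gave the list's level, and its SE came from the pooled spread of these means. Lists were tested with camera from limma (preset correlation between genes 0.01, at least 5 measured members, Benjamini-Hochberg over the 37 lists). Beside it stand camera with the correlation estimated from the data and fry, which tests whether the members of a list move, on balance, in one direction, without comparing them with other genes. The lists held 908 different genes, 808 of them measured under a gene name, and several lists share members.

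The tests, the lists and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and up to 10 largest falls among called genes whose groups did not overlap, a fixed set of 12 genes (Trp53, Mdm2, Mdm4, Cdkn1a, Il15, Il15ra, H2-Aa, Ciita, B2m, Cd274, Mlana and Cd8a), and up to 4 members of each list with the smallest unadjusted p. Predicted genes and clone names were counted but not named. A further called gene that the rule takes is counted but not reported here by name. Ifng, Ncr1, Cd163, Arg1, Lcp1, Arhgdib, Was, Coro1a, Bbc3, Cd80 and members of gene families such as the Toll-like receptors were named outside this rule, after their values were seen. Trp53 has no named probe here and was not analysed here. The count of members called "adjusted over the list alone" uses Benjamini-Hochberg within that list.

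The pipeline was tested on simulated data for the comparison of RG7112 with vehicle, with 10 simulated sets of 22203 probes that had the real means and a spread drawn from the fitted variance distribution, and 200 probes changed in each. It recovered 2.69% of probes changed by 0.5 on the log2 scale, 62.4% of those changed by 1 and 99.7% of those changed by 2, and on average 5.91% of calls were false. A list of p53 target genes shifted by 0.5 was called in 100% of the sets, with a mean of 0.2 other lists called per set. These sets had no correlation between genes. The number of arrays limits the precision, since 2 vehicle and 3 RG7112 arrays allow only 10 splits, and an exact permutation test of a single value could not give a p below 0.1.

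The alternatives were an intensity trend or robust fit in eBayes, array weights, quantile and cyclic loess normalization of the deposited values, leaving out probes with a mean below the 40th percentile, 1 probe per named gene, the melanocyte lineage level as a covariate, adjusted p under 0.10, a further minimum of 1.5-fold, and leaving out each tumour in turn. For lists, they were also camera with an estimated correlation, fry, camera on ranks, and the mean of all probes of a gene. The p53 list without Casp1 was added after the data were seen.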

Results

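Gene expression was measured in subcutaneous melanomas grown in C57BL/6 mice from B16.F10 cells, a mouse melanoma line that here carried luciferase and green fluorescent protein. All 5 mice received anti-PD-1, an antibody that blocks an inhibitory receptor of T cells, on days 1, 4 and 8. Of these mice, 2 also received vehicle by mouth (corn oil with 5% DMSO) and 3 received RG7112, a small molecule that blocks the binding of MDM2 to p53 and so the degradation of p53. RG7112 or vehicle was given every 2 days for 6 days, which the labels can be read to place from 2 days after tumour cell injection, and tumours were taken on day 13. The labels describe the samples as mixtures of melanoma cells and infiltrating immune cells from mice aged 10 weeks, with an RNA quality number above 9. The vehicle tumours are numbered 3 and 4 and the RG7112 tumours 1, 2 and 3, as in the labels.

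The 5 arrays had similar value distributions, with medians from 5.76 to 5.81 on the log2 scale. RG7112 replicate 1 had the widest distribution, with quartiles of 4.02 and 7.85, against 4.13 and 7.72 for vehicle replicate 3. Across genes, Pearson correlations were 0.992 between the vehicle tumours, 0.987 to 0.990 among the RG7112 tumours and 0.983 to 0.988 between groups; genes are not independent replicates. No pair of arrays was identical. The first principal component held 43.7% of the variance and placed the vehicle tumours at -24.5 and -24.0 and the RG7112 tumours at 32.7, 9.39 and 6.48. The second held 23.5% and set RG7112 replicate 3 apart, at -30.7 against 3.01 to 14.8 for the other tumours.

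The comparison asked how adding MDM2 inhibition to anti-PD-1 changed the tumour transcriptome. The gene lists with the largest shifts, all higher in RG7112 tumours, were those of interferon responses, macrophages and monocytes, and antigen presentation, in which 7 to 16 members each passed the test and 7 to 21 did not. Camera called these lists, but with an estimated correlation no list was called (smallest adjusted p = 0.130). At adjusted p under 0.05 in limma, 315 probes were higher and 7 were lower of 22203 tested, and the calls were made from 3 RG7112 and 2 vehicle tumours. The 315 probes stood for 279 named genes and 36 unnamed probes, with a median log2 fold change of 1.27. In all 322 called probes the groups did not overlap. Probes were called for differences that were large against their spread, so this separation follows largely from the selection and adds no support. For a single probe, chance gives a separation in a given direction in 10% of splits. At an unadjusted p under 0.05 in limma, 1073 probes were higher and 901 lower. Chance alone gives a share of 0.05 of all 22203 probes under that threshold, spread over both directions, so these counts hold many chance differences.

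The largest rise was in Clec12a (probe TC0600001532.mm.2), an inhibitory C-type lectin receptor of myeloid cells, from 5.18 ± 0.45 (SD, n = 2) with vehicle to 7.80 ± 0.34 (SD, n = 3) with RG7112. Its log2 fold change was 2.62 ± 0.24 (SE), or 6.15-fold (adjusted p = 0.000353). Aif1, an actin-binding protein of macrophages, rose from 4.49 ± 0.11 to 7.06 ± 0.35, a log2 change of 2.57 ± 0.20 (adjusted p = 0.000303). Slamf7, a receptor of the SLAM family found on several kinds of leukocytes, rose by 2.51 ± 0.23, and Fcgr4, an activating receptor for IgG on myeloid cells, rose by 2.48 ± 0.26. The C-type lectins Clec4a1 and Clec4a3 rose by 2.47 and 2.36, Glipr1 by 2.33, Cd180, a surface protein related to Toll-like receptors, by 2.23, the interferon-inducible GTPase Gvin1 by 2.23 and the leukocyte surface glycoprotein Cd52 by 2.16. These 10 genes had adjusted p-values from 0.000303 to 0.00849, and only Cd52 lost its call when a tumour was left out (without vehicle replicate 4, adjusted p = 0.166).

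All 7 called falls were smaller than 1 on the log2 scale. Krtap11-1 (probe TC1600002037.mm.2), a hair keratin-associated protein, fell from 4.55 ± 0.16 to 3.61 ± 0.22, a change of -0.94 ± 0.18 (SE; adjusted p = 0.0222). Dnm1, a dynamin GTPase of endocytosis best known in neurons, changed by -0.92 ± 0.16 (adjusted p = 0.0126). Among the others were Kazald1 (-0.86), Wfdc15b (-0.86), Fam13c (-0.85) and the netrin Ntn5 (-0.76). Their vehicle means lay between 4.55 and 6.01, and 5 of the 7 lay below the array medians. None of the 7 was called without vehicle replicate 3 (adjusted p from 0.0898 to 0.390) or without vehicle replicate 4 (adjusted p from 0.167 to 0.506).

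The counts depended strongly on the vehicle tumours, of which there were 2. Without vehicle replicate 3, 151 probes were higher and 1 lower, and without vehicle replicate 4, 65 were higher and 0 lower (1566 probes had an unadjusted p under 0.05), with the lone vehicle tumour assumed to vary like the RG7112 tumours. With the melanocyte lineage level as a covariate, which separated the groups by itself, 0 probes were called in limma. An unadjusted p under 0.05 was reached by 867 probes, fewer than the share of 0.05 that chance alone gives.

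Genes induced by interferon gamma, the cytokine of activated T and NK cells, showed the largest shift of the 37 lists. Of 23 measured members 16 rose, 0 fell and 7 did not pass, and adjusted over the list alone 17 rose. The list's mean level was 7.38 ± 0.25 (SD, n = 2) with vehicle and 8.55 ± 0.17 (SD, n = 3) with RG7112, a shift of 1.17 ± 0.18 (SE). The guanylate-binding proteins Gbp8 and Gbp9, which act against intracellular pathogens, rose by 2.05 ± 0.20 and 1.91 ± 0.17. Cxcl9 and Cxcl10, chemokines that attract T cells, rose by 1.74 ± 0.22 and 1.65 ± 0.21. Cd274, which encodes the PD-1 ligand PD-L1, rose from 6.80 ± 0.54 to 8.34 ± 0.40, a log2 change of 1.54 ± 0.26 (limma adjusted p = 0.0122), a call lost without vehicle replicate 4 (1.16, adjusted p = 0.267) or without RG7112 replicate 2 (1.46, adjusted p = 0.0513). Ifng itself differed by 0.38 ± 0.28 and did not pass (adjusted p = 0.790). For the list, camera gave an adjusted p of 8.68e-34, and an adjusted p = 0.140 with an estimated correlation. Genes of the type I interferon response, which acts against viruses, shifted by 0.78 ± 0.13, with 10 of 31 members higher, 0 lower and 21 not passing, and 25 higher adjusted over the list alone. Trim30a rose by 2.12 ± 0.21, Zbp1, a sensor of nucleic acids, by 1.28 ± 0.17, and the antiviral protein Rsad2 by 1.10 ± 0.16. Camera gave an adjusted p of 3.32e-32 for this list, and an adjusted p = 0.140 with an estimated correlation. Without vehicle replicate 4, Cxcl9, Cxcl10, Zbp1 and Rsad2 were not called (adjusted p = 0.0816, 0.0751, 0.0816 and 0.111), and without vehicle replicate 3 Zbp1 (adjusted p = 0.0570) and Rsad2 (adjusted p = 0.0850) were not. Macrophage and monocyte markers moved in the same tumours, by 0.96 ± 0.18.

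Both pathways of antigen presentation were higher. Of 16 measured genes of MHC class II presentation, which displays extracellular peptides to CD4 T cells, 7 rose, 0 fell and 9 did not pass, and 9 rose adjusted over the list alone. H2-Aa (probe TC1700001905.mm.2), the class II alpha chain, rose from 8.13 ± 0.34 (SD, n = 2) to 10.1 ± 0.08 (SD, n = 3), a log2 change of 1.98 ± 0.18 (SE; limma adjusted p = 0.000356). H2-Eb1 rose by 2.16 ± 0.23, H2-Ab1 by 1.80 ± 0.17, and H2-DMa, which helps load peptides, by 2.10 ± 0.17. Ciita, the master regulator of class II genes, differed by 0.95 ± 0.23 and did not pass (adjusted p = 0.0863). Over all settings its difference ran from 0.62 to 1.43. The list shifted by 0.84 ± 0.11 (camera adjusted p = 2.49e-14, and adjusted p = 0.140 with an estimated correlation). MHC class II was a focus of the study, so this list is not independent evidence of its direction. Of 20 genes of MHC class I presentation, which displays intracellular peptides to CD8 T cells, 10 rose, 0 fell and 10 did not pass, and 17 rose adjusted over the list alone. The immunoproteasome subunit Psmb8 rose by 1.98 ± 0.26, the peptide transporter subunit Tap1 by 1.55 ± 0.19 and the non-classical class I gene H2-T22 by 1.41 ± 0.15. B2m, the class I light chain, differed by 0.63 ± 0.16 from a high level of 12.0 and did not pass (adjusted p = 0.106). The class I list shifted by 0.89 ± 0.09 (camera adjusted p = 1.61e-28, and adjusted p = 0.130 with an estimated correlation). The calls of Psmb8 (adjusted p = 0.104) and Tap1 (adjusted p = 0.0570) were lost without vehicle replicate 4. The shift of 0.96 ± 0.18 in macrophage and monocyte markers, cells that express class II genes, stood beside both lists.

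**Figure D1:**
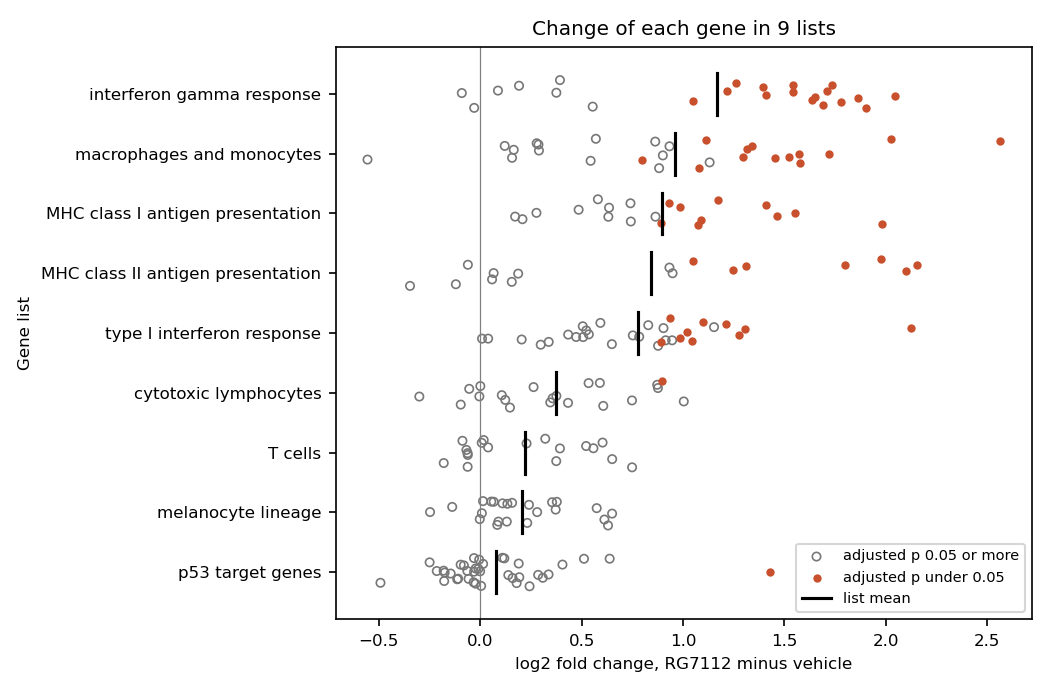
Log2 fold change (RG7112 minus vehicle, horizontal axis) of each measured gene in 9 of the 37 gene lists (vertical axis; height within a list is random). Filled points passed adjusted p under 0.05, open points did not, and black bars are list means; 16 of 23 interferon gamma response genes passed, 0 of 18 T cell genes and 1 of 38 p53 target genes.

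Markers of macrophages and monocytes shifted by 0.96 ± 0.18 (SE), from 6.22 ± 0.18 (SD, n = 2) to 7.18 ± 0.21 (SD, n = 3). Of 27 measured members 13 rose, 0 fell and 14 did not pass; adjusted over the list alone 20 rose and 1 fell. Beside Aif1, Ly6c2, a marker of inflammatory monocytes, rose by 2.03 ± 0.26, the macrophage receptor Adgre1 by 1.58 ± 0.18 and the high-affinity IgG receptor Fcgr1 by 1.34 ± 0.17. The gene that fell adjusted over the list alone was the scavenger receptor Cd163, with -0.56 ± 0.17 (adjusted p = 0.240 over all genes). Without vehicle replicate 4, Ly6c2 (adjusted p = 0.0666), Adgre1 (adjusted p = 0.0574) and Fcgr1 (adjusted p = 0.0846) were not called. Arg1, an enzyme of alternatively activated macrophages, differed by 0.12 ± 0.29 (Cd163 and Arg1 were named after their values were seen). Camera gave an adjusted p of 1.77e-30 for the list, and an adjusted p = 0.140 with an estimated correlation. 

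Lists of T cells, regulatory T cells, cytotoxic lymphocytes, NK cells, and checkpoints and exhaustion were called higher too, with shifts from 0.22 to 0.45, but most of their members did not pass. Their difference from the macrophage list was not tested. The list of B cells and plasma cells was not called (-0.05 ± 0.12, camera adjusted p = 0.625). Lymphocyte lists had dim signals, with vehicle means of 4.14 for NK cells, 4.46 for B cells, 4.55 for cytotoxic lymphocytes and 4.91 for T cells. The macrophage list was at 6.22 and the array medians at 5.76 to 5.81, so the sizes of these shifts are not directly comparable. Without dim probes the NK and B cell lists had fewer than 5 members and were not tested. Of 21 genes of cytotoxic lymphocytes 1 rose, the CD8 chain Cd8b1 (0.90 ± 0.18, adjusted p = 0.0314), a call that was lost whichever of the 5 tumours was left out. Cd8a differed by 0.87 ± 0.25 (adjusted p = 0.184), the killing protein perforin, Prf1, by 0.75 ± 0.20 and Nkg7 by 0.88 ± 0.22. The list shifted by 0.37 ± 0.09 (camera adjusted p = 1.17e-06, and adjusted p = 0.140 with an estimated correlation), with 8 members higher adjusted over the list alone. Its shift was 0.70 without dim probes and 0.57 with the melanocyte lineage covariate. Of 18 T cell genes 0 passed over all genes and 0 adjusted over the list alone; Cd3e differed by 0.75 ± 0.21 and Cd3g by 0.52 ± 0.17. The T cell list shifted by 0.22 ± 0.05 (camera adjusted p = 0.00349, and adjusted p = 0.156 with an estimated correlation), and it was not called without vehicle replicate 4 (0.18, adjusted p = 0.0509) or without dim probes (adjusted p = 0.104). The NK cell list shifted by 0.45 ± 0.11 (camera adjusted p = 1.12e-06, and adjusted p = 0.165 with an estimated correlation), and 2 of its 17 members rose, 5 adjusted over the list alone. These were Fcer1g (1.98 ± 0.22), a signalling chain also used by Fc receptors of myeloid cells, and the lectin-like receptor Klrb1b (1.70 ± 0.30), while the NK receptor Ncr1 differed by 0.07 ± 0.16. Of 18 checkpoint and exhaustion genes 3 rose, 6 adjusted over the list alone, and the list shifted by 0.40 ± 0.04 (camera adjusted p = 5.30e-07, and adjusted p = 0.140 with an estimated correlation). The 3 were Vsir (1.14 ± 0.16), a checkpoint ligand that myeloid cells also express, the nuclear receptor Nr4a2 (1.00 ± 0.20) and the ectonucleotidase Entpd1 (0.84 ± 0.17), which macrophages and endothelium express too. Entpd1 was also the only called member of 14 genes in the regulatory T cell list, which shifted by 0.25 ± 0.09 (camera adjusted p = 0.00110, and adjusted p = 0.258 with an estimated correlation), had 2 members higher adjusted over the list alone, and was not called without vehicle replicate 4 (0.16, adjusted p = 0.0578), while its shift was 0.39 without dim probes. The calls of Vsir, Nr4a2, Entpd1 and Klrb1b were each lost without vehicle replicate 3 and without vehicle replicate 4, and that of Fcer1g without vehicle replicate 4 (adjusted p = 0.0539). The macrophage list's shift of 0.96 stood beside all of these lists.

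Inflammatory mediators moved in part. Of 30 chemokines 4 rose, 0 fell and 26 did not pass, and 5 rose adjusted over the list alone. They were Cxcl9, Cxcl10, Ccl3 (1.78 ± 0.25), a chemokine made by activated macrophages and lymphocytes, and Cxcl16 (0.91 ± 0.17), and the list shifted by 0.32 ± 0.09 (camera adjusted p = 0.000123, and adjusted p = 0.165 with an estimated correlation). Of 27 NF-kB target and cytokine genes 4 rose, 0 fell and 23 did not pass, and 5 rose adjusted over the list alone. They were the cytokine Tnf (1.43 ± 0.17), the adhesion molecule Vcam1 (1.30 ± 0.17), the macrophage growth factor Csf1 (0.91 ± 0.18) and Birc3 (0.90 ± 0.18), an inhibitor of cell death. The calls of Ccl3 (adjusted p = 0.0907), Tnf (adjusted p = 0.0598) and Vcam1 (adjusted p = 0.104) were lost without vehicle replicate 4, and those of Cxcl16, Csf1 and Birc3 without either vehicle tumour and without at least 1 RG7112 tumour. This list shifted by 0.24 ± 0.04 (camera adjusted p = 0.000195, and adjusted p = 0.140 with an estimated correlation). The macrophage list's shift of 0.96 ± 0.18 stood beside both lists.

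No list of melanoma or stromal genes was called lower. The melanocyte lineage list, 23 genes of pigment cells that B16 melanoma expresses, was at 10.1 ± 0.04 (SD, n = 2) with vehicle and 10.3 ± 0.04 (SD, n = 3) with RG7112, a shift of 0.21 ± 0.04 (SE). No member passed over all genes, and 2 were higher adjusted over the list alone. The median member differed by 0.13, and 1 member, Kit (0.57 ± 0.23), is also in the list of mast cells and eosinophils. Mlana, a melanosomal antigen, differed by 0.24 ± 0.16, and Bace2 and Ednrb had the smallest p-values, with differences of 0.65 ± 0.15 and 0.63 ± 0.17. Camera gave an adjusted p of 0.000327, and an adjusted p = 0.188 with an estimated correlation. Of 23 endothelial genes 1 rose, the VEGF receptor Kdr (1.01 ± 0.19), a call lost without either vehicle tumour and without RG7112 replicate 2 or 3; 6 rose adjusted over the list alone. The endothelial list shifted by 0.29 ± 0.04 (camera adjusted p = 4.08e-06, and adjusted p = 0.140 with an estimated correlation). Of 27 fibroblast and matrix genes 0 passed by either count, and the list shifted by 0.24 ± 0.15 (camera adjusted p = 6.94e-05, and adjusted p = 0.360 with an estimated correlation); RG7112 replicate 2, at 0.01 above the vehicle mean, did not share the shift, which was 0.16 without RG7112 replicate 3. The adipocyte list shifted by 0.42 ± 0.22 (camera adjusted p = 0.000505, and adjusted p = 0.267 with an estimated correlation), and was not called without RG7112 replicate 3, the tumour with its highest level (0.26, adjusted p = 0.0944). Of its 16 members 2 rose, 3 adjusted over the list alone. They were the nuclear receptor Pparg (1.78 ± 0.16) and the fatty acid-binding protein Fabp4 (1.18 ± 0.19), which macrophages and, for Fabp4, endothelium also express. The call of Fabp4 was lost without vehicle replicate 4 (adjusted p = 0.216). The adipokine Adipoq differed by 1.10 ± 0.50 and did not pass.

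Genes of DNA replication and G1/S shifted by 0.16 ± 0.13 (camera adjusted p = 0.00107, and adjusted p = 0.497 with an estimated correlation) and those of G2/M by 0.09 ± 0.10 (camera adjusted p = 0.0422, and adjusted p = 0.689 with an estimated correlation). In both lists 0 of 34 members passed by either count, and RG7112 replicate 2 lay 0.02 and 0.06 below the vehicle mean. The replication list was not called without RG7112 replicate 3 (0.10, adjusted p = 0.0590) and shifted by 0.25 without RG7112 replicate 2. The G2/M list was not called without vehicle replicate 3 (0.034, adjusted p = 0.473), RG7112 replicate 1 (0.045, adjusted p = 0.266) or RG7112 replicate 3 (0.060, adjusted p = 0.161), and shifted by 0.15 and 0.16 without vehicle replicate 4 and RG7112 replicate 2. Its call also ended with array weights (adjusted p = 0.119), quantile normalization (0.037, adjusted p = 0.316), cyclic loess (adjusted p = 0.235) and without dim probes (adjusted p = 0.158). With the melanocyte lineage covariate both lists were instead called lower, G2/M at -0.44 (adjusted p = 0.00276) and replication at -0.38 (adjusted p = 0.0310). That covariate nearly follows the groups, and with it the median SE of a probe was 0.58 instead of 0.17, so these reversals are imprecise. Genes of the unfolded protein and integrated stress response made the only list called lower, with a shift of -0.14 ± 0.06 (camera adjusted p = 0.0422, and adjusted p = 0.462 with an estimated correlation). None of its 27 members passed by either count; the stress-induced transcription factor Ddit3 differed by -0.59 ± 0.17, the cystine transporter Slc7a11 by -0.54 ± 0.16 and asparagine synthetase, Asns, by -0.52 ± 0.16. The call was lost without vehicle replicate 3 (-0.11), RG7112 replicate 2 (-0.12) or RG7112 replicate 3 (-0.11), and with camera on ranks (adjusted p = 0.127).

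The target pathway of RG7112 was examined at harvest as a check of the treatment. If dosing began 2 days after injection, as the labels can be read, its 6 days ended before the harvest on day 13. The values below then describe p53 targets at harvest and cannot tell whether p53 was active during dosing. Of 38 measured p53 target genes 1 rose, 0 fell and 37 did not pass, and 2 rose adjusted over the list alone. The called gene was Casp1 (1.43 ± 0.20, adjusted p = 0.00367), a protease that matures inflammatory cytokines and is also interferon-inducible; its call was lost without vehicle replicate 4 (adjusted p = 0.121). Mdm2, itself a p53 target, was at 9.27 ± 0.02 (SD, n = 2) with vehicle and 9.60 ± 0.39 (SD, n = 3) with RG7112, a difference of 0.34 ± 0.21 (adjusted p = 0.738). Cdkn1a, the cell cycle inhibitor p21, differed by -0.11 ± 0.17 (adjusted p = 0.924) and Mdm4, a relative of Mdm2, by 0.17 ± 0.26 (adjusted p = 0.926). With a tumour left out, Mdm2 ranged from 0.15 (without RG7112 replicate 1) to 0.54 (without RG7112 replicate 3), Mdm4 from -0.048 (without vehicle replicate 4) to 0.46 (without RG7112 replicate 3), with -0.013 without RG7112 replicate 2, and Cdkn1a from -0.23 (without RG7112 replicate 1) to -0.0027 (without vehicle replicate 3), none of them called. The list shifted by 0.08 ± 0.12 and was not called (camera adjusted p = 0.222), and its median of -0.01 had the opposite sign to its mean. RG7112 replicate 1 lay 0.26 above the vehicle mean, and RG7112 replicates 2 and 3 lay at 0.01 and -0.04. Without RG7112 replicate 3 the shift was 0.13 and passed the threshold (adjusted p = 0.0347), and without RG7112 replicate 1 it was -0.015 (adjusted p = 0.739). Without dim probes it was 0.020, and with the melanocyte lineage covariate -0.30, not called in either.

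Of 10 genes of the IL-15 axis, a cytokine system that sustains NK and CD8 T cells, 1 rose by either count, the receptor chain Il2rb (0.95 ± 0.19, adjusted p = 0.0357), a call lost without either vehicle tumour and without RG7112 replicate 1 or 3. Il15ra differed by 0.56 ± 0.24 (adjusted p = 0.525), and Il15, at a low level of 4.01 ± 0.22 with vehicle, by 0.16 ± 0.24 (adjusted p = 0.921). Over all settings Il15ra ran from -0.45 to 0.76 and Il15 from -0.31 to 0.36, so neither kept its sign. Both lowest values came with the melanocyte lineage covariate, which nearly follows the groups. Whichever tumour was left out, Il15ra stayed above 0, while Il15 lay below 0 without RG7112 replicate 1. The list shifted by 0.21 ± 0.09 (camera adjusted p = 0.0422, and adjusted p = 0.267 with an estimated correlation), and was not called without vehicle replicate 4 (0.15), RG7112 replicate 1 (0.15) or RG7112 replicate 3 (0.21). Its call also ended with array weights (adjusted p = 0.0600), quantile normalization (adjusted p = 0.101), cyclic loess (adjusted p = 0.0958), camera on ranks (adjusted p = 0.0733) and without dim probes (adjusted p = 0.119). IL-15 was a focus of the study too, so this list is not independent evidence either.

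**Figure D2:**
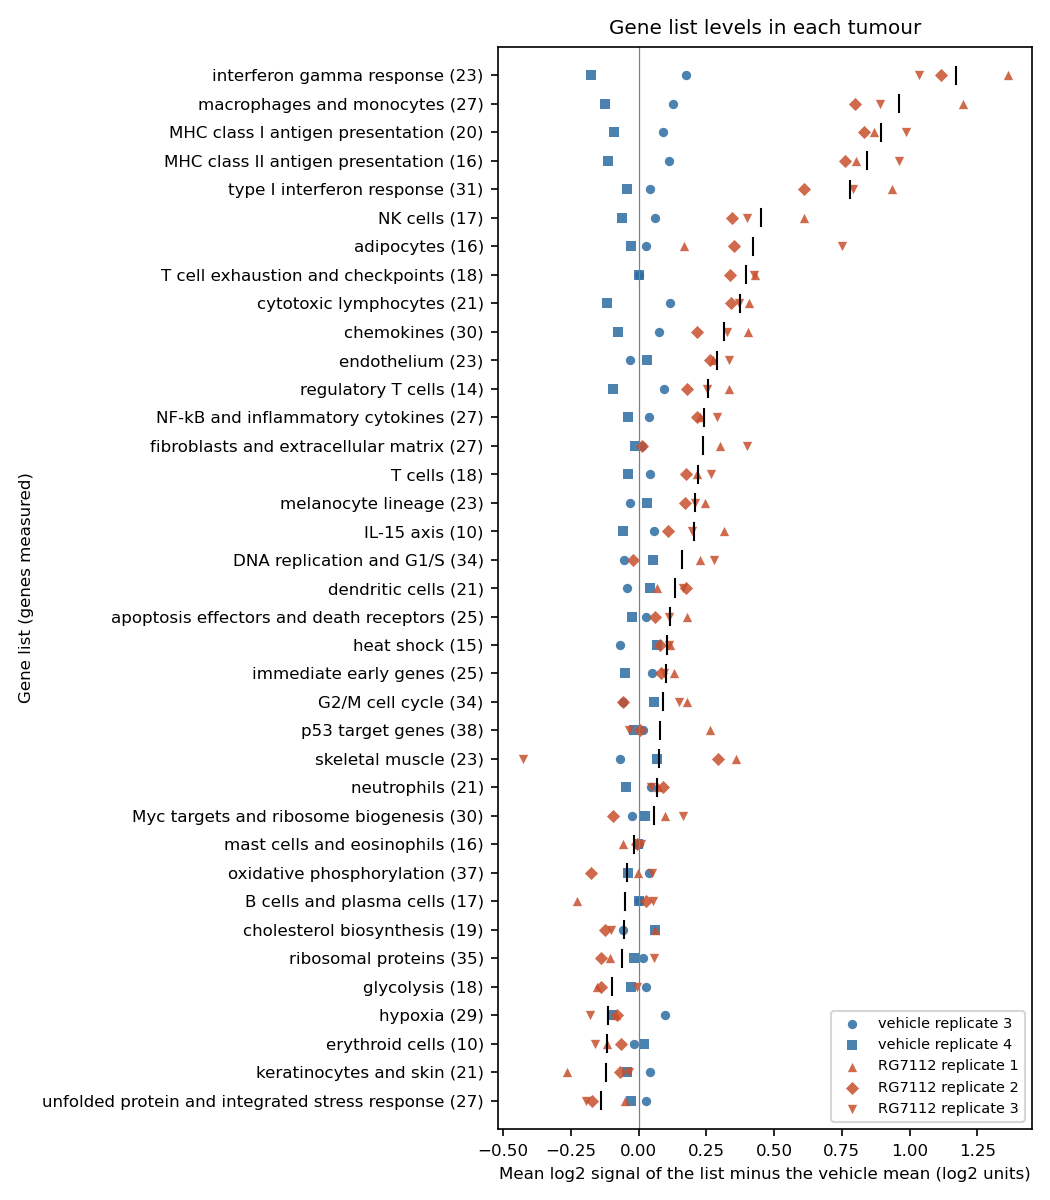
Mean log2 signal of each of the 37 gene lists (vertical axis, measured genes in brackets) in each of the 5 tumours, as the difference from the mean of the vehicle tumours (horizontal axis, log2 units). Blue points are vehicle tumours, orange points RG7112 tumours and black bars the RG7112 mean. In 20 lists all RG7112 tumours lay above both vehicle tumours, and in 2 all lay below. For a single list chance gives either in 10% of splits, but the lists share members and the same 5 tumours, so they are not independent.

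In all, camera called 19 lists higher and 1 lower, and with an estimated correlation it called 0, with a smallest adjusted p of 0.130. With fry, 7 lists were higher and 0 lower: MHC class I, MHC class II, interferon gamma, type I interferon, checkpoints and exhaustion, endothelium, and NF-kB. The macrophage list missed that threshold (fry adjusted p = 0.0507). The remaining 17 lists were not called. Besides the p53 targets these were dendritic cells, keratinocytes and skin, hypoxia, heat shock, apoptosis effectors and death receptors, immediate early genes, erythroid cells, Myc targets and ribosome biogenesis, glycolysis, ribosomal proteins, neutrophils, skeletal muscle, cholesterol biosynthesis, oxidative phosphorylation, B cells and plasma cells, and mast cells and eosinophils. Their shifts ran from -0.12 to 0.13, with camera adjusted p-values from 0.0874 to 0.700. Members that rose in them were the dendritic and myeloid integrin Itgax (0.98 ± 0.20), the death ligand Tnfsf10 (1.31 ± 0.24), which is also interferon-inducible, and Nr4a2, and all 3 calls were lost without vehicle replicate 4. Leaving out a tumour brought some of these lists past the threshold: hypoxia (-0.21), keratinocytes (-0.16) and heat shock (0.17) without vehicle replicate 4, immediate early genes (0.15) without vehicle replicate 3, dendritic cells (0.17) without RG7112 replicate 1, hypoxia (-0.13) and Myc targets (0.13) without RG7112 replicate 2, and skeletal muscle (0.33) and ribosomal proteins (-0.12) without RG7112 replicate 3. The hypoxia list was also called lower with an intensity trend (adjusted p = 0.0289), quantile normalization (adjusted p = 0.0233), cyclic loess (adjusted p = 0.0171) and without dim probes (adjusted p = 0.0390). The dendritic cell list was called higher after quantile normalization (adjusted p = 0.0323) and cyclic loess (adjusted p = 0.0315), and heat shock with camera on ranks (adjusted p = 0.0477). With the melanocyte lineage covariate the calls of the lists of checkpoints (shift 0.25), NK cells (0.18), T cells (0.27), regulatory T cells (0.24), chemokines (0.21), endothelium (0.20), fibroblasts (-0.19), the IL-15 axis (0.014) and the stress response (-0.27) ended, with adjusted p-values from 0.166 to 0.867, while cholesterol biosynthesis (-0.51, adjusted p = 0.0127) was called lower and B cells higher (0.37, adjusted p = 0.0424). The type I interferon list kept its call with a smaller shift (0.36, adjusted p = 0.0218), as did macrophages (0.64), while adipocytes (0.81) had a larger one. The mean and the median differed in sign in 3 lists, those of p53 targets, dendritic cells and neutrophils.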

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

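The alternatives were planned, except the p53 list without Casp1, which was added after the data were seen. The counts of probes higher and of lists higher, which are 315 and 19, stayed within 1.5 times in every setting not named here. Among 322 called probes, 303 were also called after quantile normalization and 310 after cyclic loess. With the melanocyte lineage covariate, 0 probes were called in either direction (limma; 867 at an unadjusted p under 0.05), 9 lists were higher and 3 lower. The median SE of a probe was then 0.58 instead of 0.17, while the called probes that were higher had a median log2 change of 1.28 instead of 1.27, so these calls ended because the covariate nearly follows the groups. With it, lists of G2/M (-0.44), DNA replication (-0.38), fibroblasts (-0.19) and B cells (0.37) changed sign and were called in at least 1 of the fits; the cause was not tested. Of the lists called in neither fit, 9 turned as well, among them p53 targets (-0.30), Myc targets (-0.32), keratinocytes (0.31), hypoxia (0.14), skeletal muscle (-0.24) and heat shock (-0.13). Counts of probes lower, 7 as reported, were 16 with array weights, 4 with cyclic loess, 2 without dim probes and 29 at adjusted p under 0.10. Lists lower, 1 as reported, were 2 with an intensity trend, quantile normalization, cyclic loess or no dim probes, and 0 with camera on ranks. With an estimated correlation, 0 lists were called higher and 0 lower, and the MHC class II shift of 0.84 had an adjusted p of 0.140. Over all settings that adjusted p ran from 2.42e-17 to 0.140. With fry, 7 lists were higher and 0 lower. For checkpoints, endothelium, NF-kB and T cells the estimated correlation was -0.048, -0.024, -0.013 and -0.015, below the preset 0.01. This argues against a higher correlation between genes as the cause of the lost camera calls of these lists. In the other lists that lost a call the estimate lay above the preset, for example at 0.52 for interferon gamma. Apart from this, the cause of these changes was not tested.

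Leaving out each tumour in turn gave 65 to 273 genes changed (counted as probes), 65 to 268 genes higher and 0 to 5 genes lower, all from fewer samples. All 322 called probes kept their sign in each of these 5 fits, as they had to, since their groups did not overlap. The vehicle tumours mattered most, with 65 probes called without vehicle replicate 4 and 152 without vehicle replicate 3, where the lone vehicle tumour was assumed to vary like the others. Lists higher ranged from 17 to 20 and lists lower from 0 to 3. The p53 shift ranged from -0.015 to 0.13 and passed the threshold without RG7112 replicate 3 only. Without Casp1 it was 0.04 (camera adjusted p = 0.413). Of 167 named genes, 58 were called, and 39 of these lost the call without vehicle replicate 4, 20 without vehicle replicate 3, and 12 to 15 without an RG7112 tumour. None changed sign while called.

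No paired analysis was possible because the groups share only replicate number 3. The log2(value + 16) setting was not run, since the values already were log2. Of the 7 falls, 5 had dim signals, with vehicle means between 4.55 and 5.35.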

Other observations

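Some gene families of innate immune cells, chosen after the fold changes were seen, are given as counts of called members only; no family was tested as a set, and some members, such as Fcgr1, are also in a fixed list. All 4 measured Fc gamma receptors were higher, Fcgr4 (2.48 ± 0.26, SE) most, and so were 6 of 9 members of the p200 interferon-inducible family, which includes sensors of cytosolic DNA, and 5 of 9 Slam family receptors. Of 18 Ms4a genes 5 were higher, of 12 Toll-like receptors 4 (Tlr1, Tlr7, Tlr8 and Tlr13, of which the last 3 sense RNA in endosomes), of 9 Schlafen genes 3, and of 11 Clec4 lectins 3. None of these families had a member called lower. After quantile or cyclic loess normalization the medians of all 7 families stayed above 0, and the counts moved by at most 1.

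Some of the tests below were chosen only after the result was seen: those of cell shares for the rise of 315 probes, the bound for reading that rise after quantile normalization (which itself was chosen beforehand), the p53 list without Cd80 and Casp1, and the comparison of the ATF4 branch with melanocyte genes. The others were set before their result was seen.

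The rise of 315 probes was weighed against 3 explanations. A lower share of melanoma cells, with the mix of other cells unchanged, would raise the markers of all other cell types alike. The macrophage list instead rose above the mean of the fibroblast and endothelium lists by 0.70 ± 0.18 (SE), and the melanocyte list was higher by 0.21 ± 0.04. The macrophage list was set against the others after its shift, the largest of the cell type lists, had been seen. This contrast therefore cannot decide against an even rise of all other cell types. More leukocytes would themselves lower the share of melanoma cells, and cell shares were not measured. The wider value distribution of RG7112 replicate 1 is argued against as the whole cause, since 308 probes were higher after quantile normalization, 299 of them among the 315. More leukocytes would raise a list of 24 measured pan-leukocyte genes, none in a fixed list, which shifted by 0.92 ± 0.07. Of these 14 were called (Lcp1, among the brighter ones at 8.29 with vehicle, rose by 1.00 ± 0.17) and 10 not. Arhgdib (-0.02 ± 0.17) and Was (-0.07 ± 0.19) lay below 0 and Coro1a differed by 0.35 ± 0.18. This test was chosen after the result was seen, and the called members are among the 315 probes, so it decides nothing. Among fixed leukocyte lists, macrophages shifted by 0.96 and T cells, cytotoxic lymphocytes and NK cells by 0.22 to 0.45. Dendritic cells (0.13), neutrophils (0.07), mast cells and eosinophils (-0.02) and B cells (-0.05) were not called. Neutrophils, mast cells and eosinophils, and B cells had dim signals, with vehicle means of 4.52, 4.25 and 4.46. Their missing calls therefore do not show that these cells were unchanged. Whether the tumours held more leukocytes, or each leukocyte expressed more interferon-induced genes, or both, stays open. The 10 splits of the 5 tumours are too few for a share under 0.05. The real split called 322 probes and is the 1 split that reached that number, and the highest other split called 0. Every other split mixes vehicle and RG7112 tumours, so any difference between the groups, whatever its cause, widens the spread there. Few calls in those splits were therefore likely from the start, and the contrast adds no support.

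The p53 target list lay above the other tumours in RG7112 replicate 1, by 0.27 over the mean of the other 4, with 21 of its 38 members highest in that tumour (Mdm2 was 0.63 above the mean of the other tumours and Cdkn1a 0.23, while Perp lay 0.40 and Bbc3 0.33 below it). The count of highest members was not set against all genes or repeated after quantile normalization, and that array had the widest distribution, so the count is only descriptive. The value distribution of that array does not account for most of the list's excess, as 0.22 remained after quantile normalization. Whether it exceeds the general spread of genes in that array stays open: it lay at percentile 100 of 10000 random lists matched on mean expression, but this list was looked at for its excess and its members move together, so that percentile decides nothing. Without the inflammation-linked members Cd80 and Casp1 it was 0.22. Other lists were highest in this tumour too, above the vehicle mean by 1.36 for interferon gamma (1.12 and 1.03 in RG7112 replicates 2 and 3), 0.94 for type I interferon (0.61 and 0.79), 1.20 for macrophages (0.80 and 0.89) and 0.61 for NK cells (0.34 and 0.40), and it lay apart on the first principal component (32.7 against 9.39 and 6.48). Whether the excess goes with these, or with p53 activity at harvest, stays open; drug or p53 protein levels were not tested here, and it rests on 1 tumour.

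The stress response list was split, after its values were seen, into 2 branches. One is driven by ATF4, the transcription factor of the integrated stress response. The other holds chaperones and other genes of protein quality control in the endoplasmic reticulum. The ATF4 branch was lower by a shift of -0.38 ± 0.10 (SE), with 12 of 13 members below 0 and none called, against 0.08 ± 0.06 for the 14 genes of the other branch. Relative to the melanocyte list the branch shifted by -0.59 ± 0.11. As the branch was picked after its values were seen, this difference alone cannot decide against less melanoma RNA. The melanocyte list itself was higher by 0.21 ± 0.04. The arrays' value distribution is argued against as the whole cause, as the shift was -0.41 ± 0.10 after quantile normalization. Only these 2 explanations were weighed, and the whole stress response list shifted by -0.14 ± 0.06. A lower integrated stress response in RG7112 tumours is therefore no more than a hypothesis from the same data. Other causes, and the cells it would lie in, were not tested.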
